A study of Mus musculus with 6 samples.

How the data were processed

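Small RNA libraries of mouse prefrontal cortex were made from total RNA extracted with Trizol, with the TruSeq Small RNA kit, and sequenced on an Illumina HiSeq instrument, per the labels' protocols. The same protocols state that the ACGT101-miR program removed adapter dimers, junk, low complexity reads, rRNA, tRNA, snRNA, snoRNA and repeats from the reads. The genome build, the miRBase release, the mapping settings and the number of mismatches allowed are not given in the sources used here. The protocols speak of 9 libraries, of which 6 were analysed here: 3 from mice given water (0 mg per kg) and 3 from mice given PS-NP at 50 mg per kg. Groups and library numbers were taken from the sample titles and treatment labels. Nothing in the labels says that each library came from a separate animal, so the p-values measure only the spread between these libraries, which could in part be technical.

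The deposited table lists, per the file headers, a raw and a norm value for each small RNA and library. The raw values are estimated counts: per the deposited file they are reads per entry, and where 1 sequence is listed on several entries its reads have been divided among them. This was tested on the values: 78 of the 1013 sequences stood on several of the 1115 entries, always with equal values. Of the values of those sequences, 44.4% were whole numbers (within 1e-06) as listed and 89.1% after summing, and over all entries the share was 86.8% before and 95% after summing. The norm values are a normalized signal made by the authors, equal to the raw value times 1 factor per library (0.911, 1.142 and 1.27 for the controls and 1.17, 0.869 and 0.714 for PS-NP, from the values). How the factors were set is not given in the sources used here, and norm values were used only for an alternative scaling. Another 3 lines of the table were not analysed here.

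Entries of 1 sequence were summed, a choice made after the table was seen, and the sums were rounded to whole numbers. The tests had been planned for counts or normalized values; for estimated counts the count test was used on the rounded sums. Low values need care: among 3769 whole values above 0 of sequences on a single entry, 2 were under 5 and 254 were exactly 5. A listed 0 can therefore stand for a few reads, and no upper limit was computed from a 0. Sequences named for mouse (mmu, 772), for another species (140) or predicted from the reads (101) were kept; the other-species names held 0.23% to 0.32% of reads and the predicted ones at most 0.024%. Closely related miRNAs, such as let-7 members, may share reads when a read carries an error or an edited end, and sequences encoded at several hairpins cannot be assigned to 1 of them.

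Sequences with at least 10 reads in at least 3 of the 6 libraries were tested, 639 in all. Library totals ran from 6170654 to 9905746 reads. Counts were scaled by TMM (factors 0.863 to 1.115) and tested with edgeR's quasi-likelihood test, with Benjamini-Hochberg adjustment at 0.05. The common biological coefficient of variation was 30.6%. CPM values use TMM-scaled library sizes, the error beside a mean is the SD, and the error beside a log2 difference is its SE or 95% interval from the fit. Groups share the numbers 1 to 3 in the labels, and the fit did not use them.

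Lists of miRNAs for cell types, brain regions, other organs, blood, families and clusters were fixed before the data were examined, as were the tests, the alternatives and the rule for named miRNAs. The 19 lists were neuron-enriched, activity-regulated, oligodendrocyte, astrocyte, microglia and blood leukocyte, erythroid, vascular, choroid plexus and ependyma, miR-200 family, hindbrain and spinal cord, hypothalamus and pituitary, miR-183 cluster, muscle and liver, inflammation and stress, let-7 family, miR-29 family, miR-30 family, miR-17/92 and related clusters, and the Dlk1-Dio3 imprinted cluster. They hold 267 names, of which 198 were tested; some miRNAs are on several lists, and most lists for other tissues hold miRNAs that cortex also makes. A sequence belonged to a list when its mouse name, without isoform suffix, equalled a member, and the most abundant one was taken where several shared a name. By this rule the name let-7a-5p fell on the entry with the let-7c-5p sequence. Lists with at least 3 tested members were tested by camera (limma) on log2 CPM with a preset correlation of 0.01, with an estimated correlation beside it, and by fry. List medians and numbers of members higher come from the fit on log2 CPM, while log2 differences of single miRNAs come from edgeR.

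The rule named every miRNA past the adjusted threshold and, as fewer than 24 passed, those of lowest unadjusted p up to 24, at most 12 per direction. It also named the 10 most abundant, the 2 to 4 members of lowest unadjusted p of each tested list, and the 3 hairpins of lowest p in arm usage. Other miRNAs in the text were chosen after their values were seen. Arm usage was log2 of (5p reads + 1)/(3p reads + 1) for 151 hairpins with both arms tested, compared with limma. For weak arms with listed reads, the added 1 understates the ratio. For an arm listed without reads, the ratio can be understated or overstated, since such a value can stand for a few reads. Shares of reads and numbers of detected sequences were compared by exact two-sided permutation tests.

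Positions come from an exact match of each listed sequence to the miRNA hairpins of GENCODE M21 on GRCm38, 1-based; 688 of 1013 sequences matched. The build the authors mapped to is not given in the sources used here, so these positions are a match made here. Host genes were sought on the same DNA strand only, among protein-coding and long noncoding genes.

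The tests were run on simulated counts drawn from the real means, library sizes and spread, in 10 tables of 639 miRNAs with 200 changed. For the PS-NP comparison, edgeR called 56.9% of 2-fold and 92.4% of 4-fold changes, with 2.9% false among calls. With 200 of 639 miRNAs changed, the adjusted threshold is easier to pass than where few change. These shares therefore do not give the power to find a change in a few miRNAs. Camera called the let-7 list in 100% of 20 tables with that list raised 1.5-fold, and no list in tables with no change. The simulated miRNAs were drawn independently of each other. In the data, list members can move together (estimated correlation 0.881 for the choroid plexus and ependyma list, and 0.06 for the let-7 family). The simulation therefore does not show how often camera at the preset correlation calls lists falsely here. The arm test called 79.5% of 4-fold shifts over 151 hairpins, with a median of 1 false hairpin per table. No pair of libraries agreed within sampling noise (chi-square per degree of freedom at least 75.1), so none was treated as 1 library deposited again. That covers counting error only and does not show that the libraries are separate samples. Alternatives covered the filter, scaling, test, left-out libraries, library numbers, mouse names, list tests and pseudocount of the arm ratio. Alternatives for the pseudocount on normalized values were not run, since estimated counts were tested. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Reads were not mapped again, and targets of the miRNAs were not tested.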

Results

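Small RNA was sequenced from the prefrontal cortex of male C57BL/6 mice, an inbred laboratory strain. The animals had been given nano-polystyrene (PS-NP, plastic particles of nanometre size) by gavage into the stomach every day for 6 months, at 50 mg per kg body weight, or water as the control. Each group had 3 libraries, and the labels give an age of 30 weeks. The control libraries held 9445601, 6170654 and 6441890 reads assigned to miRNAs, and the PS-NP libraries held 7726729, 8440665 and 9905746. The table listed 1013 distinct small RNA sequences, of which 772 carried a mouse miRNA name. Of these sequences, 639 had enough reads to be tested, and they held at least 99.98% of the reads of every library. Pearson's r of log2 CPM (the reads of a miRNA scaled to a common library size) between libraries, computed across miRNAs that are not independent replicates, was 0.971 to 0.984 within groups and 0.967 to 0.984 between groups.

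The most abundant miRNA in the cortex of both groups was miR-125b-5p, a miRNA enriched in brain, at 207900 ± 47740 CPM in controls and 193300 ± 65580 CPM with PS-NP (SD, n = 3 each). It was followed by miR-128-3p, a neuronal miRNA, at 111800 ± 3204 and 113800 ± 19730 CPM, and by miR-127-3p, from the imprinted Dlk1-Dio3 region, at 59170 ± 6071 and 60380 ± 11310 CPM. The neuronal miRNA miR-124-3p stood at 44820 ± 6452 CPM in controls and 41590 ± 8682 CPM with PS-NP, and miR-9-5p at 24770 ± 2224 and 28410 ± 4553 CPM. The log2 difference between groups was −0.10 (SE 0.27) for miR-125b-5p, 0.03 (SE 0.17) for miR-128-3p, −0.11 (SE 0.20) for miR-124-3p and 0.20 (SE 0.17) for miR-9-5p. The other members of the 10 most abundant, miR-26a-5p, miR-30c-5p, miR-125a-5p, miR-434-3p and miR-29a-3p, had log2 differences of 0.21 (SE 0.19), −0.05 (SE 0.19), −0.34 (SE 0.32), −0.16 (SE 0.15) and 0.15 (SE 0.18). None of the 10 passed the edgeR test of all miRNAs, whose smallest adjusted p was 0.906. As each library was left out in turn, the log2 difference ran from −0.42 to 0.06 for miR-125b-5p, −0.08 to 0.14 for miR-128-3p, −0.09 to 0.16 for miR-127-3p, −0.25 to 0.03 for miR-124-3p and −0.21 to 0.09 for miR-30c-5p. It ran from 0.06 to 0.36 for miR-26a-5p, −0.76 to −0.11 for miR-125a-5p, −0.23 to −0.09 for miR-434-3p, 0.04 to 0.25 for miR-9-5p and 0.03 to 0.25 for miR-29a-3p.

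The main comparison asked which miRNAs of the prefrontal cortex differ after PS-NP exposure, since the series was built to find marker miRNAs of brain injury. The cortex of PS-NP mice held 1.45 times the miR-152-3p, 1.38 times the let-7f-5p and 0.731 times the miR-667-3p of controls, and none of these differences passed the adjusted test. No miRNA passed an adjusted threshold of 0.05 among the 639 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment, smallest adjusted p 0.906). At an unadjusted p under 0.05 there were 15 sequences, 9 with a higher and 6 with a lower mean in PS-NP cortex. That is fewer than chance alone gives, which is a share of 0.05 of the 639 tested. The lower ones include a pair of miR-466f-3p sequences with identical reads, which count as 1 observation. Once the trend with GC content was removed from each library, a correction chosen after the data were seen, 13 sequences had an unadjusted p under 0.05. Of the 15 above, 9 were among them. DESeq2 called 0, with 15 at an unadjusted p under 0.05, and limma-voom called 0, with 17. The 24 miRNAs of lowest unadjusted p all missed the adjusted threshold.

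The lowest unadjusted p belonged to miR-152-3p, a member of the miR-148/152 family. It measured 165.5 ± 13.4 CPM in controls and 240 ± 19.0 CPM with PS-NP (SD, n = 3 each), a log2 difference of 0.54 (95% interval 0.15 to 0.92). Its sequence TCAGTGCATGACAGAACTTGG matched GRCm38 chromosome 11, 96850439 to 96850459, in an intron of Copz2. Next stood let-7f-5p at 4275 ± 318 and 5888 ± 308 CPM, a log2 difference of 0.46 (0.13 to 0.79). Its sequence occurs on chromosome 13, 48537889 to 48537910, in an exon of the lincRNA 6720427I07Rik, and on chromosome X, 151912353 to 151912374, in an intron of Huwe1, and counts cannot separate these copies. Its relative let-7g-5p, from an intron of Wdr82 on chromosome 9, 106178846 to 106178867, measured 12170 ± 1368 and 15760 ± 911 CPM, a log2 difference of 0.37 (0.02 to 0.72).

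Among miRNAs of vessels and connective tissue, miR-126a-3p measured 1540 ± 246 CPM in controls and 2138 ± 254 CPM with PS-NP, a log2 difference of 0.47 (0.07 to 0.88). This endothelial miRNA lies within Egfl7 on chromosome 2, 26591402 to 26591422, in a stretch annotated as exon in a transcript of that gene. The mesenchymal miRNA miR-199b-3p, whose sequence is shared by the Mir199a-1, Mir199a-2 and Mir199b hairpins, measured 57.2 ± 12.9 and 87.0 ± 8.89 CPM, a log2 difference of 0.60 (0.11 to 1.10). The opposite strand miR-199a-5p measured 37.7 ± 6.30 and 53.0 ± 6.07 CPM, a log2 difference of 0.49 (0.02 to 0.97). Its sequence occurs in Mir199a-2 on chromosome 1, 162217844 to 162217866, in an exon of the noncoding transcript Dnm3os. It also occurs in Mir199a-1 on chromosome 9, 21496537 to 21496559, where no host gene was found on the same DNA strand. Genes on the other DNA strand were not searched, and counts cannot separate these copies.

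Within the Dlk1-Dio3 imprinted cluster on chromosome 12, a large group of miRNAs made in neurons, the lowest p values went to members on opposite sides. miR-667-3p (109720061 to 109720083) measured 859.6 ± 52.1 CPM in controls and 628.2 ± 49.0 CPM with PS-NP, a log2 difference of −0.45 (−0.80 to −0.10), and −0.23 after the GC trend of each library was removed. miR-411-5p (109710190 to 109710210) measured 758.8 ± 55.3 and 984 ± 127 CPM, a log2 difference of 0.38 (0.00 to 0.75). No host gene was found at either position on the same DNA strand. miR-1247-5p, from an exon of the nearby noncoding transcript Dio3os (110278094 to 110278115), measured 16.1 ± 2.35 and 7.38 ± 5.04 CPM, a log2 difference that ran from −1.69 without PS-NP library 3 to −0.68 without PS-NP library 1.

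Of the other miRNAs in this group with a positive log2 difference, miR-3083-5p had 0.63 (SE 0.26), miR-29b-3p 0.42 (SE 0.19) and miR-708-3p 0.46 (SE 0.22). Without PS-NP library 3 the log2 difference was 0.27 for miR-29b-3p and 0.30 for miR-708-3p. A pair of sequences listed under other species belonged here as well: cpo-miR-16a-5p, close in sequence to mouse miR-16-5p, with 0.58 (SE 0.21), and cgr-miR-1260_1ss9GT with 1.64 (SE 0.82). The latter rested on the first PS-NP library, at 83.7 CPM against 7.33 to 14.6 CPM in the other 5, and its log2 difference without that library was −0.24. Those with a negative log2 difference were miR-193b-3p (−0.52, SE 0.22), let-7b-3p (−0.43, SE 0.19), miR-328-3p (−0.38, SE 0.19), miR-3084-3p (−0.92, SE 0.33), miR-6944-3p (−0.59, SE 0.26), miR-3572-3p (−1.05, SE 0.48), miR-216b-5p (−1.33, SE 0.62) and miR-6948-3p (−1.18, SE 0.60). The log2 difference of miR-193b-3p was −0.28 without control library 3, and that of miR-328-3p was −0.19 without control library 2 and −0.08 with the GC trend removed. A pair of miR-466f-3p sequences from the Sfmbt2 intron on chromosome 2 carried identical reads in every library, so they count as 1 observation, with a log2 difference of −0.82 (SE 0.30).

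**Figure D1:**
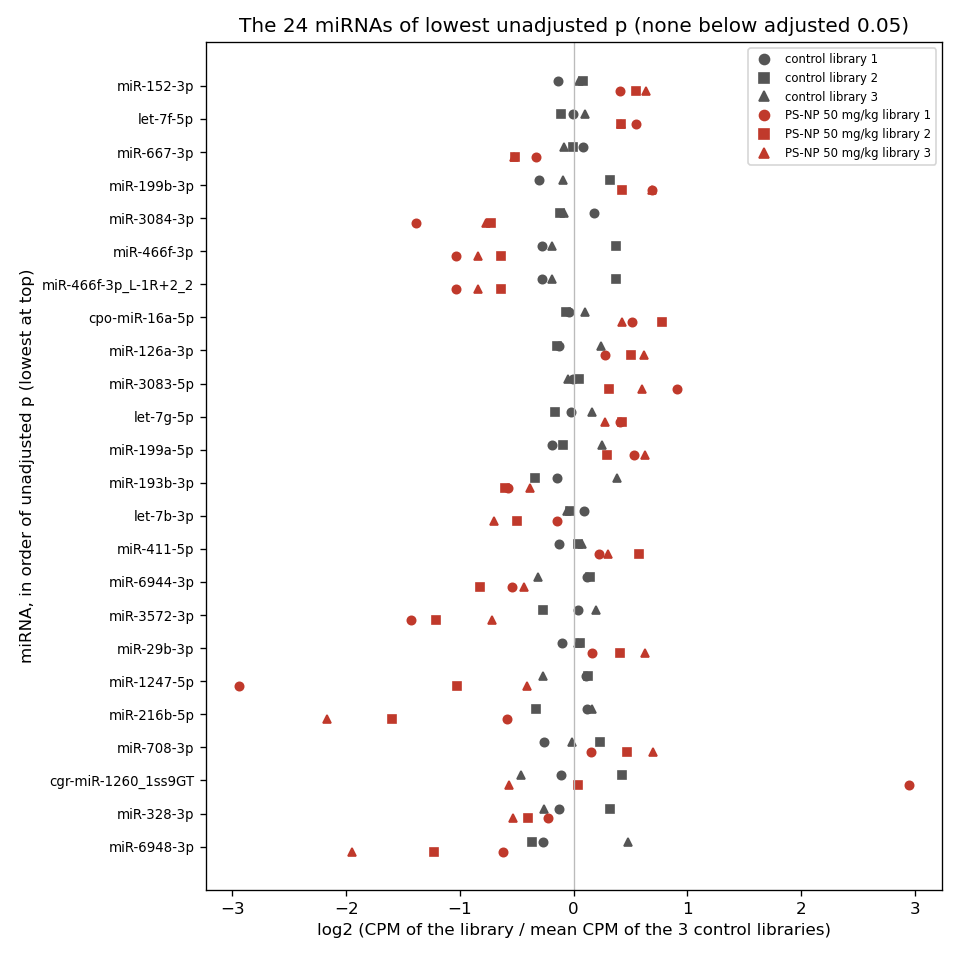
Each point is 1 library, placed by the log2 ratio of its CPM to the mean CPM of the 3 control libraries, for the 24 miRNAs of lowest unadjusted p, with controls in grey and PS-NP in red. The 3 PS-NP libraries lie to the right of all controls for miR-152-3p and let-7f-5p and to the left for miR-667-3p, and no miRNA shown passed the adjusted test (smallest adjusted p 0.906).

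In 61 of the 639 miRNAs (9.5%) the 3 PS-NP libraries all lay on one side of the 3 controls, where chance gives 10%. The median size of the log2 difference was 0.23, and 96.6% of miRNAs differed by less than 2-fold. The median 95% interval of a single miRNA, not adjusted for the number of tests, reached 0.64 log2 units to either side, and 0.45 for the 228 miRNAs with a mean of at least 100 CPM.

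Of the 18 miRNA lists tested, the let-7 family, whose members share a seed sequence and are abundant in differentiated cells, had the only call. The median log2 difference of its 9 tested members was 0.28, and 7 were higher in PS-NP cortex (camera with a preset correlation of 0.01, adjusted p = 0.0249). The call was lost with an estimated correlation (adjusted p = 0.581 with an estimated correlation), and the adjusted p of fry was 0.257 for a shared direction and 0.0738 for change in either direction. That correlation was estimated at only 0.06, so the loss does not show that let-7 members moved together. For the astrocyte list, estimated at −0.033, the unadjusted camera p also rose, from 0.0361 at the preset correlation to 0.0956 with the estimated one. Besides let-7f-5p and let-7g-5p, miR-98-5p measured 51.9 ± 1.96 CPM in controls and 65.7 ± 4.93 CPM with PS-NP, and let-7i-5p measured 4730 ± 366 and 5744 ± 444 CPM. At the other end, let-7b-5p measured 6988 ± 674 and 6999 ± 1545 CPM, and let-7e-5p 2413 ± 158 and 2354 ± 395 CPM. No member was called adjusted over the list alone (0 of 9, smallest adjusted p 0.107 from edgeR) or over all miRNAs (0 of 9), with 2 at an unadjusted p under 0.05.

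The let-7 members average 38.7% GC against 50.6% for all tested miRNAs, and the log2 differences of the 639 miRNAs ran against GC content (Spearman's rho −0.467 across miRNAs, which are not independent replicates). After the GC trend of each library was removed, a correction chosen after the data were seen, the list median was 0.19 and the adjusted p of camera 0.495. The list also lost its call without control library 2 (adjusted p of camera 0.277), without PS-NP library 1 (0.198) and without PS-NP library 2 (0.0576). Without control library 3, 4 lists passed at the preset correlation: let-7 family, vascular, muscle and liver, and miR-30 family. Of these 4 lists 0 passed there with an estimated correlation (adjusted p = 0.514 with an estimated correlation for each of them).

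The vascular list, of endothelial and smooth muscle miRNAs, had a median log2 difference of 0.43 with 6 of 8 members higher and did not pass (camera adjusted p 0.0592; adjusted p = 0.581 with an estimated correlation). After miR-126a-3p came miR-143-3p, a smooth muscle miRNA, at 2360 ± 369 CPM in controls and 3078 ± 649 CPM with PS-NP, and miR-145a-3p at 35.2 ± 6.93 and 48.5 ± 9.75 CPM. The more abundant miR-145a-5p, from the same hairpin, measured 1041 ± 229 and 952.9 ± 118 CPM, and miR-139-5p 16070 ± 922 and 13710 ± 1108 CPM. Without control library 3 the vascular adjusted p of camera was 0.00546 at the preset correlation (adjusted p = 0.514 with an estimated correlation). The list for muscle and liver, organs outside the brain, had a median of 0.26 with 6 of 7 higher (camera adjusted p 0.0707), where miR-192-5p measured 48.2 ± 7.30 and 62.6 ± 12.6 CPM and miR-194-5p 132.7 ± 9.31 and 156.9 ± 17.4 CPM. Adjusted over the list alone, 0 members passed in either list, and over all miRNAs 0 passed. Without PS-NP library 3 the log2 difference was 0.18 for miR-143-3p (0.38 in all libraries), 0.29 for miR-145a-3p (0.46) and 0.18 for miR-192-5p (0.38), and without PS-NP library 2 it was 0.15 for miR-194-5p (0.24).

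The glial and blood lists did not pass. Astrocyte miRNAs had a median log2 difference of 0.14 with 7 of 8 higher (camera adjusted p 0.162), led by miR-29b-3p at 74.0 ± 4.24 CPM in controls and 98.6 ± 15.7 CPM with PS-NP. Microglia and blood leukocyte miRNAs had a median of 0.23 with 5 of 8 higher (camera adjusted p 0.487), where miR-142a-5p measured 9.17 ± 2.10 and 13.5 ± 5.58 CPM and miR-155-5p, induced in activated immune cells, measured 3.17 ± 0.773 and 5.17 ± 2.68 CPM. The list for inflammation and stress had a median of 0.11 with 8 of 13 higher (camera adjusted p 0.487), and its member miR-200c-3p measured 13.6 ± 17.9 and 3.67 ± 4.24 CPM. That difference rested on control library 3, at 34.4 CPM, and turned from a log2 of −1.93 to 0.12 without it. Oligodendrocyte miRNAs had a median of −0.12 with 2 of 7 higher (camera adjusted p 0.686), where miR-338-3p measured 158.5 ± 31.5 and 177.3 ± 21.2 CPM and miR-219a-5p 2.62 ± 2.00 and 1.29 ± 1.15 CPM. Erythroid miRNAs had a median of 0.01 with 2 of 4 higher (camera adjusted p 0.968), and the red cell miRNA miR-451a measured 59.0 ± 29.0 and 59.6 ± 11.5 CPM. Of this list, miR-16-5p measured 843 ± 272 and 1007 ± 112 CPM and miR-486b-5p 838.4 ± 178 and 714.2 ± 251 CPM. In these 5 lists 0 members passed adjusted over the list alone and 0 over all miRNAs. As each library was left out in turn, the microglia and leukocyte median ran from 0.01 (without control library 2) to 0.29, the log2 difference of miR-142a-5p from 0.18 (without PS-NP library 3) to 0.81 and that of miR-155-5p from 0.25 (without PS-NP library 2) to 1.02. The microglia and leukocyte median turned to −0.11 when only miRNAs with a mean of at least 100 reads were tested. Over the left-out libraries the log2 difference ran from 0.00 to 0.27 for miR-338-3p, −1.54 to −0.15 for miR-219a-5p, 0.08 to 0.54 for miR-16-5p and −0.56 to −0.04 for miR-486b-5p, and the medians from 0.09 to 0.19 for astrocyte, −0.01 to 0.22 for inflammation and stress, −0.18 to 0.01 for oligodendrocyte and −0.11 to 0.22 for erythroid miRNAs.

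Neuronal lists did not pass either. Neuron-enriched miRNAs had a median log2 difference of 0.08 with 12 of 19 higher (camera adjusted p 0.487), where miR-9-3p measured 660.2 ± 151 CPM in controls and 857 ± 76.1 CPM with PS-NP and miR-369-5p 494.8 ± 29.8 and 572.8 ± 20.98 CPM. Activity-regulated miRNAs, which include the CREB targets miR-132 and miR-212, had a median of −0.09 with 1 of 8 higher (camera adjusted p 0.686). Of these, miR-485-5p measured 762 ± 105.7 and 636.7 ± 69.7 CPM, miR-212-5p 1569 ± 422 and 1416 ± 207 CPM, and miR-132-3p 7060 ± 241 and 6924 ± 2432 CPM. The Dlk1-Dio3 imprinted cluster had a median of 0.01 with 41 of 79 higher (camera adjusted p 0.994), and camera's direction was down although median and mean lay above 0. In these 3 lists 0 members passed adjusted over the list alone and 0 over all miRNAs. With single libraries left out, the medians ran from 0.02 to 0.21 for neuron-enriched, −0.20 to 0.06 for activity-regulated and −0.10 to 0.03 for Dlk1-Dio3 miRNAs, and the Dlk1-Dio3 median was −0.01 at a mean of at least 100 reads. Over the left-out libraries the log2 difference ran from 0.21 to 0.54 for miR-9-3p and −0.36 to −0.03 for miR-212-5p.

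Among families and clusters, the miR-30 family had a median log2 difference of 0.13 with 8 of 11 higher (camera adjusted p 0.301), where miR-30e-3p measured 224.9 ± 21.6 CPM in controls and 280 ± 12.1 CPM with PS-NP and miR-30b-5p 1114 ± 248 and 1248 ± 65.1 CPM. The miR-29 family had a median of 0.10 with 5 of 7 higher (camera adjusted p 0.685), where miR-29c-3p measured 47.3 ± 8.19 and 56.9 ± 6.94 CPM. The proliferation-linked miR-17/92 cluster and its paralogs had a median of −0.12 with 5 of 12 higher (camera adjusted p 0.968). In these clusters miR-17-5p measured 51.7 ± 5.79 and 65.5 ± 18.4 CPM, and miR-363-3p 8.76 ± 13.4 and 2.05 ± 1.41 CPM, with 24.2 CPM in control library 3 alone. In these 3 lists 0 members passed adjusted over the list alone and 0 over all miRNAs. The miR-30 median was 0.01 without control library 2 and without PS-NP library 2, and 0.32 without control library 3. With single libraries left out, the medians ran from 0.03 to 0.19 for the miR-29 family and −0.10 to 0.11 for the miR-17/92 clusters, whose median was 0.15 at a mean of at least 100 reads. Over the left-out libraries the log2 difference ran from 0.14 to 0.38 for miR-29c-3p, 0.04 to 0.35 for miR-30b-5p and 0.07 to 0.45 for miR-17-5p.

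**Figure D2:**
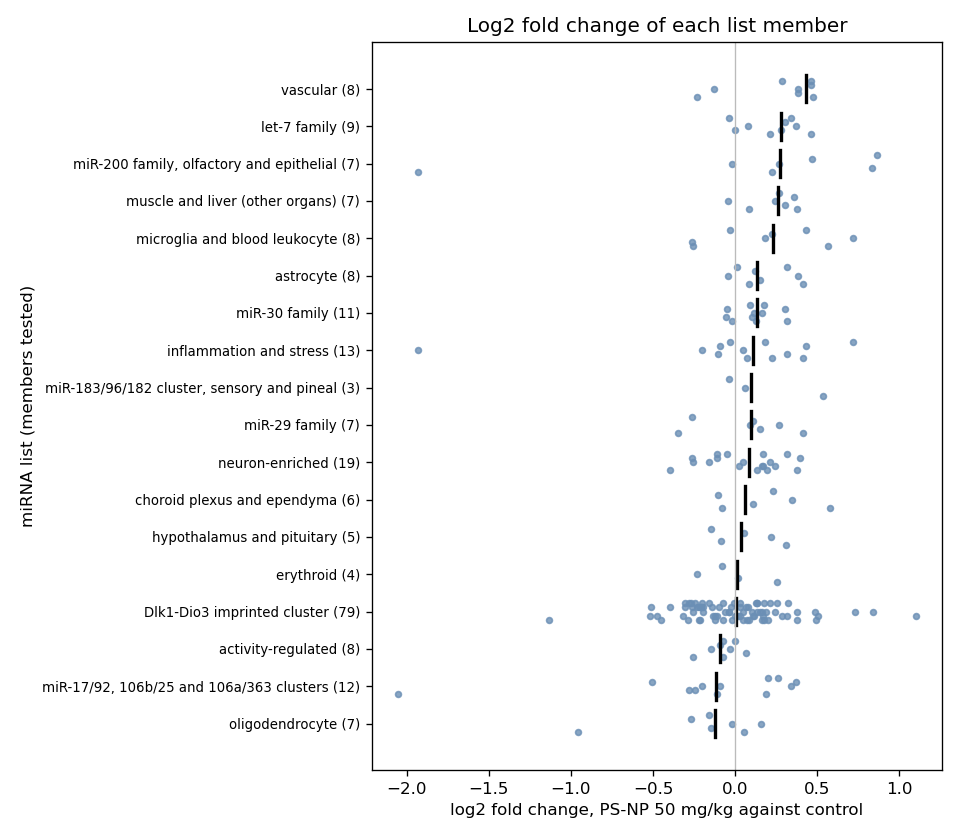
Each point is the edgeR log2 difference (PS-NP against control, 3 libraries each) of 1 member of a miRNA list, with the number of tested members in brackets. The black bar is the list median from the separate fit on log2 CPM, so it can differ from the median of the points shown. Medians range from −0.12 for the oligodendrocyte list to 0.43 for the vascular list, and the let-7 family has a median of 0.28.

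Lists for neighbouring tissue varied widely between libraries of both groups. The choroid plexus miRNA miR-204-5p, from an intron of Trpm3, measured 1760, 5604 and 3249 CPM in controls and 2048, 7199 and 4266 CPM with PS-NP. With it, the choroid plexus and ependyma list had a median log2 difference of 0.06 with 4 of 6 higher (camera adjusted p 0.964), and miR-34c-5p of ciliated cells measured 253.6 to 474.2 and 147.2 to 866.6 CPM. The list for hypothalamus and pituitary had a median of 0.03 with 3 of 5 higher (camera adjusted p 0.748), where miR-7a-5p measured 506.8 to 962.8 and 403.9 to 1348 CPM and miR-7a-1-3p 39.5 ± 5.82 and 48.8 ± 2.69 CPM. The list of the miR-200 family and other olfactory and epithelial miRNAs had a median of 0.28 with 5 of 7 higher (camera adjusted p 0.686). Its member miR-200b-3p measured 126.8, 29.0 and 154.5 CPM in controls and 240.2, 164.0 and 26.3 CPM with PS-NP. Another member of that list, miR-203-3p, which is not of the miR-200 family, measured 49.9 ± 7.97 and 60.0 ± 4.18 CPM.

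The sensory and pineal miR-183 cluster had a median of 0.10 with 2 of 3 higher (camera adjusted p 0.846), with miR-183-5p at 8.26 ± 2.78 and 8.52 ± 5.61 CPM and miR-96-5p at 0.806 ± 1.40 and 1.11 ± 0.973 CPM. The hindbrain and spinal cord list had only 2 members with enough reads for a list test of 3: miR-10b-5p at 13.2 ± 11.1 and 16.0 ± 1.60 CPM and miR-10a-5p at 12.7 ± 3.15 and 14.0 ± 1.06 CPM. In the 4 lists of neighbouring tissue and sensory cells that were tested, 0 members passed adjusted over the list alone and 0 over all miRNAs. As each library was left out in turn, the median ran from −0.30 to 0.44 for the choroid plexus list, −0.22 to 0.24 for the hypothalamus list, −0.35 to 0.996 for the miR-200 family and −0.33 to 0.25 for the miR-183 cluster, and the hypothalamus median was −0.04 with the GC trend removed. Over the left-out libraries the log2 difference ran from −0.19 to 0.84 for miR-204-5p, 0.03 to 1.02 for miR-34c-5p, −0.37 to 0.54 for miR-7a-5p, −0.62 to 0.40 for miR-183-5p and −0.10 to 1.12 for miR-96-5p.

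**Figure D3:**
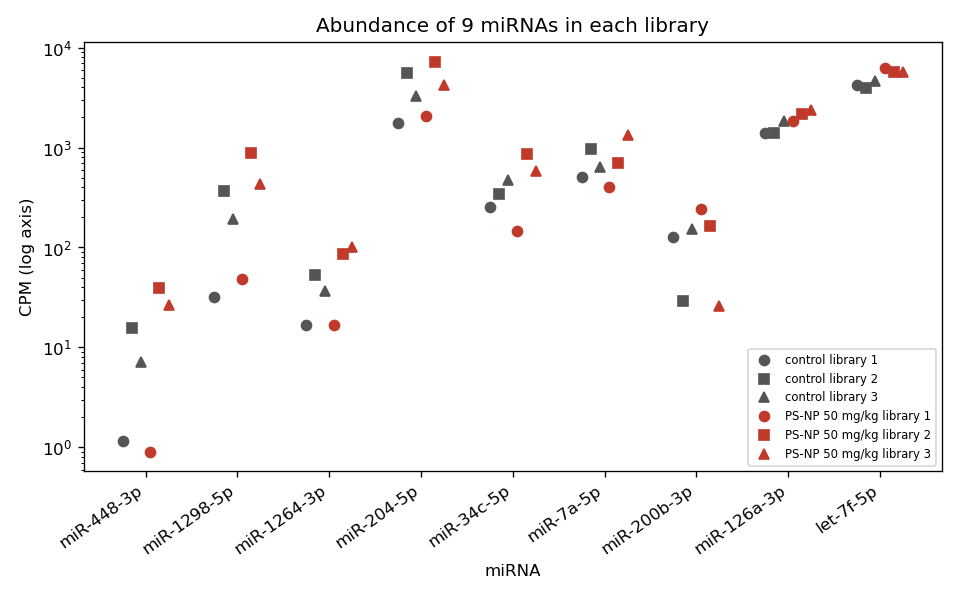
CPM on a log axis of 9 miRNAs in each of the 6 libraries, with controls in grey and PS-NP in red. The set was picked after the values were seen: miR-1298-5p runs from 31.7 to 884.5 CPM and miR-204-5p from 1760 to 7199 CPM with both groups overlapping, while let-7f-5p runs from 3963 to 6243 CPM.

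The overall make-up of the miRNA pool was compared between groups by exact permutation tests, whose smallest two-sided p with 3 against 3 libraries is 0.1. The 10 most abundant miRNAs, from miR-125b-5p to miR-29a-3p, took 60.8 ± 1.65% of reads in controls and 60.0 ± 2.53% with PS-NP (SD, n = 3 each, exact p = 0.7). miR-125b-5p alone took 20.4 ± 2.83% and 19.0 ± 3.62% (n = 3 each, exact p = 0.6). The number of distinct sequences detected was 763.3 ± 37.1 in controls and 781.7 ± 59.9 with PS-NP (n = 3 each, exact p = 0.8). Both differences, −0.738 percentage points and 18.3 sequences, were smaller than the spread within groups. The first was 0.0883 without control library 1 and 0.0915 without PS-NP library 3, and the other was −1.83 without control library 3 and −9.33 without PS-NP library 3.

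Arm usage, the log2 ratio of reads from the 5p and 3p strands of a hairpin, asked whether the strand kept from each precursor differed with PS-NP. For miR-26b the ratio was 5.53 ± 0.01 in controls and 6.13 ± 0.30 with PS-NP, a difference of 0.61 (SE 0.22). It was 4.82 ± 0.67 and 5.77 ± 0.31 for miR-181d and −4.81 ± 0.20 and −4.23 ± 0.23 for miR-331 (SD, n = 3 each). These 3 hairpins, of lowest p, lie in introns of Ctdsp1 on chromosome 1 and Nanos3 on chromosome 8 and in a UTR exon of Vezt on chromosome 10. None of the 151 hairpins passed (limma, Benjamini-Hochberg adjustment, smallest adjusted p 0.749), and 7 had an unadjusted p under 0.05. Without control library 1, 1 hairpin passed: miR-1306, from an exon of Dgcr8, with a difference of −3.89 (limma adjusted p 0.0269) against −2.67 in all libraries, where its 3p strand was at 0 to 2.44 CPM. At such values the size and the call depend on the added 1 and on listed values of 0, which can stand for a few reads.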

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

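Removing the GC trend, keeping 1 entry per sequence, the authors' scaling factors, let-7a-5p as its own sequence and an estimated correlation with a library left out were alternatives chosen after the data were seen. The count of miRNAs past the adjusted threshold was 0 in edgeR and in each of the 17 alternatives, with 6 (without control library 1) to 38 (without PS-NP library 1) at an unadjusted p under 0.05; the smallest adjusted p was 0.479, without a filter. The fits with other scalings (DESeq2 size factors, library totals, the authors' factors) moved the median log2 difference of all miRNAs by less than 0.1. Of 1301 alternative values for 87 results, 1222 kept their direction and their side of the threshold, or, for counts of calls, the same count. Only the let-7 list passed in the main tests, so keeping the side was easy for most values. The total therefore says little about robustness. The direction reversed under at least 1 alternative in 24 results, and the cause was not tested. The median 95% interval of a single miRNA, not adjusted for the number of tests, was 0.64 log2 units to either side, and the part of depth in it was not tested. Other pseudocounts on normalized values were not run, because estimated counts were tested.

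The list tests called 1 list, and 0 with an estimated correlation, 0 by fry for a shared direction, 0 with the replicate block and 0 after the GC trend was removed. Leaving out each library gave 0 to 4 lists. The let-7 adjusted p ranged from 0.00397 (without PS-NP library 3) to 0.581 over these alternatives; it was 0.0199 at a mean of at least 100 reads and 0.0121 with let-7a-5p as its own sequence (adjusted p = 0.589 and 0.581 with an estimated correlation). With an estimated correlation, leaving out each library gave 0 lists (let-7 adjusted p 0.514 to 0.923). The replicate block gave 0 miRNAs, 32 at an unadjusted p under 0.05, 0 hairpins and a let-7 adjusted p of 0.0548. Libraries of the same number share only that number: their deviations from group means correlated at 0.309, 0.152 and −0.171, and 1 of 3 controls correlated best with its own number. The arm test called 0 or 1 hairpins as libraries were left out. The difference in the share of the 10 most abundant miRNAs ran from −2.19 to 0.0915 percentage points, and that in detected sequences from −9.33 to 50.2.

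Away from left-out libraries, miR-183-5p reversed with limma-voom (−0.003), the replicate block (−0.103) and the GC trend removed (−0.058), and miR-128-3p with the GC trend removed (−0.019). List medians reversed at a mean of at least 100 reads for microglia and blood leukocyte (−0.109), the miR-17/92 clusters (0.153) and Dlk1-Dio3 (−0.008), and with the GC trend removed for hypothalamus and pituitary (−0.041) and the miR-17/92 clusters (0.005).

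Leaving out each library moved the log2 difference across 0 for cgr-miR-1260_1ss9GT (−0.24 to 2.10), miR-125b-5p (−0.422 to 0.064), miR-128-3p (−0.081 to 0.14), miR-127-3p (−0.09 to 0.161), miR-124-3p (−0.255 to 0.027), miR-30c-5p (−0.21 to 0.085), miR-204-5p (−0.186 to 0.841), miR-200c-3p (−3.44 to 0.117), miR-7a-5p (−0.367 to 0.544), miR-96-5p (−0.105 to 1.12) and miR-183-5p (−0.623 to 0.397). It did so for the medians of the lists activity-regulated (−0.2 to 0.056), oligodendrocyte (−0.182 to 0.014), erythroid (−0.108 to 0.219), choroid plexus (−0.296 to 0.443), miR-200 family (−0.347 to 0.996), hypothalamus (−0.215 to 0.235), miR-183 cluster (−0.325 to 0.253), inflammation (−0.014 to 0.222), miR-17/92 (−0.096 to 0.111) and Dlk1-Dio3 (−0.103 to 0.027).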

Other observations

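For the miRNAs of the Htr2c intron, the tests against the choroid plexus, hypothalamus and pituitary, Dlk1-Dio3 and neuron-enriched lists and the treatment were chosen after the result was seen, as was the GC correction; the other tests here were chosen before their results were seen.

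Some miRNAs differed many-fold between libraries without following the groups. The gene Htr2c on chromosome X, which encodes a serotonin receptor, holds a cluster of miRNA hairpins in its introns, from 146999424 (miR-3552) to 147158301 (miR-448) on GRCm38, and 9 of its 10 listed sequences were tested. Of these, miR-1298-5p measured 31.7, 364.5 and 191.0 CPM in the control libraries and 48.3, 884.5 and 431.1 CPM with PS-NP, a range of 27.9-fold. The rarer miR-448-3p measured 1.16, 15.5 and 7.10 CPM and 0.90, 39.5 and 26.4 CPM, and miR-1264-3p measured 16.6, 52.6 and 36.9 CPM and 17.0, 85.4 and 100.2 CPM. The mean log2 CPM of the 9 was 2.65, 4.98 and 3.92 in controls and 2.43, 4.91 and 5.05 with PS-NP, a group difference of 0.28 (exact two-sided permutation p = 0.9, smallest possible 0.1, n = 3 each).

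Over the 6 libraries the mean of the Htr2c set moved with the hypothalamus and pituitary list (Pearson's r 0.952, permutation p 0.00139, adjusted over 19 relations 0.0264, Spearman's rho 1, permutation p 0.00278). The r was 0.785 without the 2 libraries farthest from the median. With the choroid plexus and ependyma list, r was 0.899 (permutation p 0.00833, adjusted 0.0791, rho 0.771, permutation p 0.103), and 0.542 without those 2 libraries. These are control library 1 and PS-NP library 1, with the lowest means of the set (2.65 and 2.43). Leaving them out narrows the range, and the libraries left are too few to tell 0.542 from 0.785. The Dlk1-Dio3 list, of miRNAs made in neurons, moved with the set as well (r 0.836, permutation p 0.0431, adjusted 0.273, rho 1, permutation p 0.00278, and 0.733 without the 2 libraries), over mean deviations of −0.156 to 0.17 log2 units. The neuron-enriched list had an r of 0.774 (permutation p 0.0875, adjusted 0.41, rho 0.543, permutation p 0.297), but −0.324 without the 2 libraries. Of the 19 relations, that with the hypothalamus and pituitary list was the only one with an adjusted p under 0.05. The mean deviations of the miR-200 family list in log2 CPM were 0.05, −1.09 and 0.86 in controls and 1.07, 0.10 and −1.004 with PS-NP.

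A candidate explanation for the spread of the Htr2c set is a varying amount of neighbouring tissue in the dissection, either choroid plexus (r 0.899) or hypothalamus (r 0.952), since both lists moved with it, but the Dlk1-Dio3 list of neuronal miRNAs (r 0.836) did so too, and these relations single out no tissue. The most abundant members of the choroid plexus and hypothalamus lists are miR-204-5p, from 1760 to 7199 CPM, and miR-7a-5p, from 403.9 to 1348 CPM, and cortex also makes these miRNAs. The data argue against depth: r with the log2 library total was −0.114 (permutation p 0.819, adjusted 0.875, rho 0.143, permutation p 0.803, and 0.517 without the 2 libraries), and control library 1 with 9445601 reads had a mean of 2.65 against 5.05 in PS-NP library 3 with 9905746. They also argue against GC content, since 94.3% of the range was left after the GC trend was removed, and against PS-NP as the whole cause, since the ranges of the groups overlapped by 2.33 log2 units. Whether tissue in the dissection varied, and which, or expression within the cortex, remains open.

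The higher let-7 family list may come in part from GC content. After the GC trend was removed its median log2 difference was 0.19 (67.6% of 0.28), and the members averaged 0.22 ± 0.18 (SD) before and 0.12 ± 0.16 after, with 6 of 9 still higher. The call ended (camera adjusted p 0.0249 before and 0.495 after) as the mean of the members came closer to 0, while the SD of the other miRNAs went only from 0.415 to 0.395, so GC content and a shift of the family cannot be told apart. Reads split wrongly among let-7 sequences stay open too. The summed reads of the 9 tested members differed by a log2 of 0.224 (SE 0.111, exact permutation p = 0.2, smallest possible 0.1). A wrong split among these 9 cannot change that sum. It leaves out let-7a-5p's own sequence, so reads moved to or from let-7a-5p can change it. The sums were 61501, 55041 and 59602 CPM in controls and 76888, 69125 and 60492 CPM with PS-NP, so PS-NP library 3 lay among the controls. Of the 10 splits of the 6 libraries, 8 called at least as many lists as the real one, which called 1 (highest other 4). The let-7 list itself had a camera adjusted p of 0.0249 in the real split and 0.0585 to 0.944 in the other 9. It was followed over the splits because the real split called it, which favours a low p there, so these values decide nothing. In any case, 10 splits are too few for a share under 0.05. PS-NP exposure stays open as well.

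The log2 differences of the 639 miRNAs were lower at higher GC content (Spearman's rho −0.467 across miRNAs, which are not independent replicates). Deviations of single libraries from the miRNA means correlated with GC at 0.334, 0.328 and −0.177 in controls and 0.024, −0.328 and −0.233 with PS-NP, so the groups overlapped. The size of rho was at least 0.467 in 2 of the 10 splits of the libraries (highest other 0.481), and 10 splits are too few for a share under 0.05. No explanation of this relation by the treatment was tested.

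The counts of miRNAs and hairpins past the adjusted threshold were set beside those of the other splits. The real split called 0 miRNAs (highest other 1) and 0 hairpins (highest other 0). All 10 splits called at least as many in both, but no count can lie below 0, so that was fixed in advance. This comparison therefore decides nothing, and 10 splits are in any case too few for a share under 0.05. The split of control libraries 1 and 3 and PS-NP library 1 against the rest called 1 miRNA, miR-1298-3p of the Htr2c set, and 108 at an unadjusted p under 0.05, against 15 in the real split. That split was singled out because it called the most of the 10. Principal component 1 (37.7% of variance) placed those 3 libraries at −3.95, −5.73 and −12.3 and the other 3 at 10.2, 3.93 and 7.84. The component comes from the same values, so it is no separate evidence. Whether the samples have a structure other than treatment was not tested.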
